A study of Rattus norvegicus with 12 samples.

How the data were processed

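The samples were 12 RNA libraries from primary cortical neuron cultures of embryonic day 18 Wistar rats, 3 in each of 4 groups. Per the labels, total RNA was depleted of ribosomal RNA, made into strand-specific libraries, pooled 4 to a lane and sequenced as single-end reads. Which libraries shared a lane is not given in the sources used here, nor is the dose or duration of TTX. The submitters' processing notes name GSNAP, DESeq2, DESeq and the rn6 genome as used by the authors, without versions.

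The deposited signal values were base coverage summed over each RefSeq transcript and divided by a size factor per library. This was read from the values: within a library they were whole multiples of 1 step, and low values clustered at multiples of 42 times that step. The step gave the size factor and 42 the read length in nt, so each value was divided by 42 to give read equivalents. Summed over all deposited entries before the size factor, libraries held 15108848 to 24787516 read equivalents. Repeated entries are counted each time, so this sum is not the number of reads sequenced. The deposited 12-library table held 18905 entries, 18697 of them distinct, for 17339 gene symbols, and the entry with the highest mean was kept for each symbol. The authors' score was a z value signed by direction. The authors' p value came with no statement of whether it was adjusted, and Benjamini-Hochberg values were computed from it where given. The other deposited values, in the 3 annotation tables, were term names with gene counts, percent of the list, enrichment p and fold. Gene names and neighbours came from a RefSeq reference for a later assembly, and coordinates on rn6 were not used here.

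Genes with at least 10 read equivalents in at least 3 libraries were kept, which left 12073 and dropped 5266. The log2 of the value plus 1 was fitted with limma 3.58.1 in R 4.3.3, with the 4 groups as the only term, 8 residual degrees of freedom, no trend and no robust option. Benjamini-Hochberg adjustment ran over the genes tested, with a two-sided threshold of 0.05. The contrasts were TTX in wild-type, TTX in knockdown, knockdown in untreated, knockdown in TTX, knockdown over both, and the interaction. These contrasts, the threshold, the filter value, the 26 gene lists, the rule for naming genes and most alternatives were set before the data were examined. The planned scale was the values as deposited, and the division by 42 was chosen after the form of the values was seen and before any test was run. On the deposited scale the filter of 10 is under 1 read.

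The numbers of the libraries were checked for pairing by correlating their deviations from their group means. TTX and untreated libraries of the same genotype and number correlated at 0.44, 0.61 and 0.85 in wild-type and at 0.78, 0.69 and 0.77 in knockdown. Between genotypes all 6 correlations were negative, so libraries were not paired there. That the libraries of a pair share a culture was inferred from the correlations within genotypes and is not stated by the labels. A fit with each culture as a term, with 4 residual degrees of freedom, a fit with culture as a random block (correlation 0.714) and a fit on culture averages were added after seeing the data. TTX values, errors and adjusted p in the text come from the fit with each culture as a term unless groups alone are named, and knockdown and interaction values come from groups alone. P-values of single genes in the fit with each culture as a term measure the spread of the paired TTX change over these cultures. Those of groups alone measure the spread between libraries, and count the TTX and untreated libraries of a culture as separate. Neither reaches beyond these cultures.

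The 26 lists covered activity genes, glutamate and GABA receptors, neuron types, ion channels, synapse machinery, histone methylation, protocadherins, retinoic acid, interferon, stress, p53, cholesterol, oxidative phosphorylation, ribosomal proteins and other cell types. They were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over 156 tests with groups alone and 104 with the pairs. At the preset correlation 73 and 59 tests passed, and 0 passed with an estimated correlation. Camera compares the statistics of list members with those of the other genes. Its p-values at the preset correlation rest on a spread over genes, and do not measure how alike the cultures were. In the protocadherin list, 13 Pcdha and 13 Pcdhg transcripts had median correlations of 0.999 across libraries within each cluster. Its counts and p-values at the preset correlation take these repeated measurements as separate genes. The ribosomal list took in 10 other genes by its name pattern. Without them the 83 ribosomal proteins had a median of -0.29 between knockdown and wild-type, 63 of 83 being lower.

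Named genes were Ehmt1, Ehmt2, Bdnf and Arc, then up to 10 raised and 10 lowered genes per contrast (5 and 5 over both treatments) with a mean of at least 100 and an adjusted p under 0.05. For the interaction, where none passed, the 3 and 3 genes with the smallest p were named at any mean. In contrasts of 3 against 3, libraries had to separate fully in group fits, or all 3 pairs had to move one way in paired fits. Up to 4 members with the smallest p were taken from a list. Some genes that met these rules are not reported here. Power was tested on simulated data with 50 changed genes per fold. At 2-fold the group fit recovered 54% of changed genes for TTX in wild-type, and the paired fit 80% with 6 false calls in 156. For knockdown over both treatments the group fit made 77 false calls in 234, and the random block 13 in 145. Alternatives covered scaling, pseudocount, filter, variance options, blocks and libraries left out. Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used for tables and plots.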

Results

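Total RNA depleted of ribosomal RNA was sequenced from primary cortical neuron cultures of embryonic Wistar rats. The 12 libraries formed 4 groups of 3: wild-type untreated, wild-type with tetrodotoxin (TTX), knockdown untreated and knockdown with TTX. TTX is a toxin that blocks voltage-gated sodium channels and so silences firing. The knockdown used a short hairpin RNA (shRNA) against Ehmt1, which encodes a histone H3 lysine 9 methyltransferase linked to Kleefstra syndrome. The sample titles name no control hairpin. Effects of a hairpin or its delivery therefore cannot be told apart from loss of Ehmt1 in any knockdown difference. Wild-type and knockdown are called genotypes here. A read equivalent is the base coverage that 1 read of 42 nt adds. Libraries held 15108848 to 24787516 read equivalents before size factors, summed over all deposited entries with repeated ones included. All levels here are read equivalents after the authors' size factors, and 12073 genes were tested. The TTX and untreated libraries with the same genotype and number deviated together, so each genotype was taken to give 3 pairs, called cultures here. That a pair came from 1 culture is inferred, as the labels do not state it. A shared lane or batch of a pair cannot be told apart from a shared culture.

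Ehmt1 (NM_001108572), the target of the knockdown, was measured first in every library. It averaged 1652 ± 104 (SD, n = 3) in wild-type untreated and 1205 ± 286 (SD, n = 3) in knockdown untreated libraries. With TTX the averages were 1872 ± 153 (SD, n = 3) in wild-type and 1289 ± 199 (SD, n = 3) in knockdown. Averaged by culture, the knockdown level was 70.8% of wild-type, 1247 ± 242 against 1762 ± 127 (SD, n = 3 cultures each), an exact two-sided permutation p of 0.1, the smallest that 3 against 3 allows. The limma log2 change over both treatments with groups alone was -0.51 (SE 0.12, adjusted p = 0.127), and all 6 knockdown libraries lay below all 6 wild-type libraries. That adjusted p lay between 0.0939 and 0.687 over its alternatives in limma. Ehmt2 (NM_212463), the partner methyltransferase of Ehmt1, differed by -0.09 (SE 0.11, adjusted p = 0.722).

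**Figure D1:**
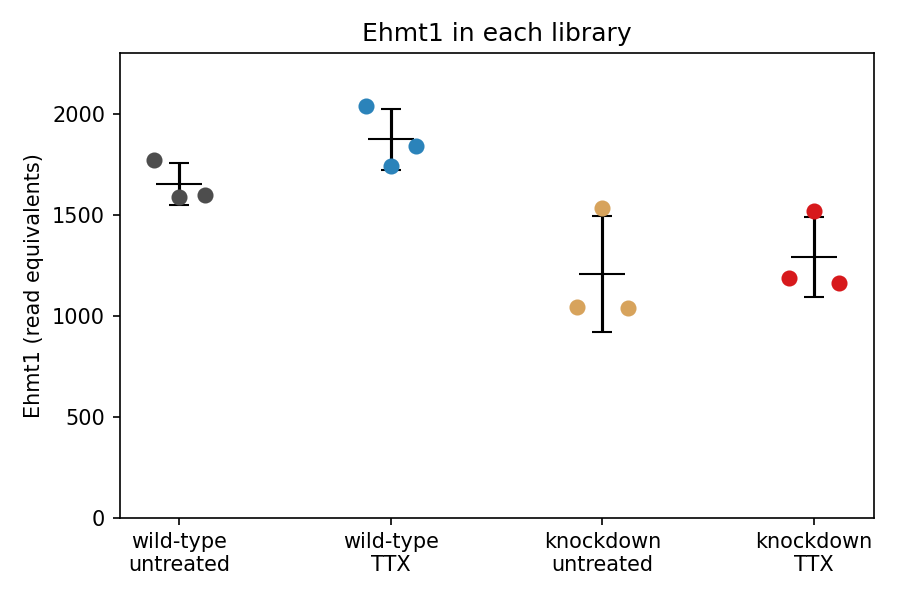
Ehmt1 level in read equivalents in each of the 12 libraries by group, with points for libraries and bars for the mean ± SD (n = 3). The knockdown libraries lay between 1037 and 1535 and the wild-type libraries between 1586 and 2039.

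The first comparison asked which transcripts change when firing is silenced in wild-type cultures. Vgf, Npy, Sst and Scg2, members of the fixed list of late activity effectors, each fell in 3 of 3 pairs. Vgf (NM_030997), a secreted neuropeptide precursor, fell by 2.69 on the log2 scale (SE 0.30, adjusted p = 0.0214), from 458 ± 256 to 62.8 ± 23.5 (SD, n = 3). Npy (NM_012614), encoding neuropeptide Y, was 5.29-fold lower (log2 -2.40, SE 0.27, adjusted p = 0.022). Sst (NM_012659), encoding somatostatin, was 3.84-fold lower (log2 -1.94, SE 0.22, adjusted p = 0.0214). Scg2 (NM_022669), a secretogranin of dense-core vesicles, was 3.32-fold lower, at 312 ± 35.3 against 1039 ± 118 (SD, n = 3; adjusted p = 0.00918).

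Other genes lowered most by TTX in wild-type were Hs3st5 (log2 -1.79), which makes a heparan sulfate sulfotransferase, Rgs4 (-1.78), a brake on G-protein signalling, and Nefh (-1.66), the heavy neurofilament. Diras2 (-1.52), a small GTPase, Wif1 (-1.49), a secreted WNT inhibitor, and Gabra5 (-1.44), a GABA-A receptor subunit, completed the 10, with adjusted p from 0.00918 to 0.0309. Among the genes raised most was Hrk (log2 0.96, SE 0.07), which encodes a pro-apoptotic BH3 protein and rose 1.95-fold. Sgca (0.87), a sarcoglycan, Plcxd2 (0.85), Adamts2 (0.78) and Adamts9 (0.74), matrix proteases, and Slc25a34 (0.75), a mitochondrial carrier, also rose. So did Steap3 (0.73), a metalloreductase, Elk1 (0.72), a transcription factor of the ERK pathway, and St8sia2 (0.72), a polysialic acid synthase, all with adjusted p from 0.00918 to 0.0475. Bdnf, a growth factor gene driven by activity, was 2.10-fold lower (log2 -1.07, SE 0.22) in 3 of 3 pairs and did not pass (adjusted p = 0.0548). Its adjusted p was 0.0318 with culture as a random block and lay between 0.0318 and 1.00 over its alternatives. Arc, an immediate early gene of synapses, had a log2 change of -0.26 (SE 0.33, adjusted p = 0.664).

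With the pairs as a term, limma called 384 of the 12073 genes, 102 higher and 282 lower with TTX, in a fit chosen after the pairing was seen. The planned model with groups alone called 11 genes on the planned scale of the deposited values, 5 higher and 6 lower. On the read-equivalent scale it called 4, all lower: Scg2 (adjusted p = 0.0194), Sst (adjusted p = 0.0497), Nell1 (log2 -1.10, adjusted p = 0.0484) and Gpr6 (log2 -2.76, adjusted p = 0.0196). Gpr6, a G-protein-coupled receptor, fell outside the naming rule because its mean was under 100, and was named after its values were seen. Leaving out 1 wild-type pair gave 31 to 58 calls in the paired fit, and leaving out 1 wild-type library gave 0 to 3 in the fit of groups.

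**Figure D2:**
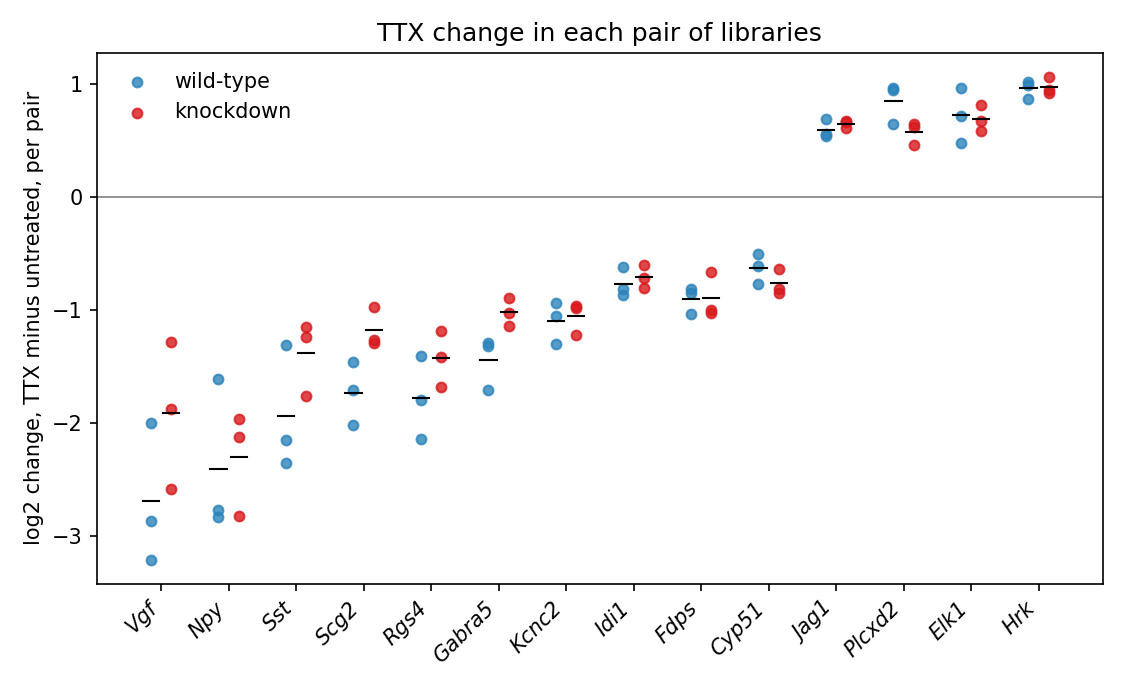
Log2 change with TTX in each pair of libraries for 14 genes, blue for wild-type and red for knockdown, with points for pairs and bars for the mean of 3 pairs. Every pair of both genotypes was below 0 from Vgf to Cyp51 and above 0 from Jag1 to Hrk.

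Among the fixed gene lists, cholesterol biosynthesis fell with TTX in wild-type. All 20 of its measured genes were lower (median log2 -0.61), 14 of them called over all genes and 20 adjusted over the list alone. They included Fdps (-0.90, SE 0.10), Mvd (-1.01, SE 0.13), Hmgcs1 (-0.76, SE 0.10) and Idi1 (-0.77, SE 0.08), enzymes of the mevalonate route. The list's camera adjusted p was 1.54e-16 at the preset correlation and 0.26 with an estimated correlation. Of the 29 late activity effectors 26 were lower (median -0.45), 6 called over all genes and 12 adjusted over the list alone, with an adjusted p of 3.98e-08 and an adjusted p = 0.26 with an estimated correlation. The 24 immediate early genes had a median of -0.12, 0 called over all genes and 4 adjusted over the list alone (1 of them higher), and an adjusted p = 0.1.

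Of 24 voltage-gated potassium channels 19 were lower (median -0.33), with 6 called over all genes and 13 adjusted over the list alone (1 of them higher), among them Kcna1 (-1.19, SE 0.11) and Kcnc2 (-1.10, SE 0.10). The adjusted p was 3.25e-06 and the adjusted p = 0.292 with an estimated correlation. Of 17 GABA receptor and scaffold genes 11 were lower (median -0.22), 3 called over all genes and 4 adjusted over the list alone. Its adjusted p was 0.00167, and adjusted p = 0.49 with an estimated correlation. Of 17 markers of GABAergic neurons, which share Sst and Npy with the late activity effectors, 13 were lower (median -0.35), with 7 called over all genes and 8 adjusted over the list alone. Gad1 (-1.09, SE 0.18), which makes GABA, and Slc32a1 (-0.89, SE 0.14), which loads it into vesicles, were among them (adjusted p = 0.000336, and adjusted p = 0.325 with an estimated correlation). Of 14 glutamatergic markers 11 were lower (median -0.23, 3 called over all genes and 7 adjusted over the list alone, 1 of them higher), including Fezf2 (-0.91, SE 0.09) and Slc17a6 (-0.84, SE 0.12), with adjusted p = 0.00165 and adjusted p = 0.26 with an estimated correlation. Of 26 presynaptic genes 23 were lower (median -0.24, 1 called over all genes and 11 adjusted over the list alone, 1 of them higher), Snap25 by -0.69 (SE 0.11), with adjusted p = 8.84e-06 and adjusted p = 0.292 with an estimated correlation.

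NMDA and metabotropic glutamate receptors had a median of -0.21 (9 of 14 lower, 2 called over all genes and 6 adjusted over the list alone, adjusted p = 0.0144). Postsynaptic scaffolds had -0.08 (17 of 23 lower, 1 called over all genes and 1 adjusted over the list alone, adjusted p = 0.0203) and sodium channels -0.20 (8 of 10 lower, 1 called higher over all genes and 6 adjusted over the list alone, 1 of them higher, adjusted p = 0.0405). Oxidative phosphorylation had -0.08 (58 of 75 lower, 0 and 0, adjusted p = 0.000763) and ribosomal proteins -0.10 (76 of 93 lower, 1 called over all genes and 1 adjusted over the list alone, adjusted p = 0.000268). In wild-type pair 2 the means of these lists, relative to all libraries, rose slightly with TTX (0.03 to 0.07 and 0.145 to 0.155). Astrocyte markers were higher (0.25, 15 of 17, 1 called over all genes and 3 adjusted over the list alone, adjusted p = 0.000429), as were progenitor and cell-cycle genes (0.25, 21 of 21, 0 called over all genes and 9 adjusted over the list alone, adjusted p = 8.57e-06). The oligodendrocyte list was at 0.33 (13 of 14 higher, 0 called over all genes and 0 adjusted over the list alone, adjusted p = 0.0128) and the interferon list at 0.35 (16 of 20 higher, 0 and 0, adjusted p = 0.0151). Each of these 9 calls was lost with an estimated correlation, the adjusted p lying between 0.29 and 0.666 with an estimated correlation. AMPA receptor, calcium channel, H3K9 methylation, protocadherin, retinoic acid, stress, p53, microglia and vascular lists did not pass (adjusted p from 0.0708 to 0.94). Among them protocadherins had a median of 0.12, a mean of -0.03 and a test pointing down. P53 targets had a median of 0.05, a mean of -0.01 and a test pointing up, and retinoic acid genes a median and mean of -0.01 and a test pointing up.

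The second comparison asked the same of knockdown cultures. Hrk rose by 0.98 on the log2 scale (SE 0.07, adjusted p = 0.0296), and Npy was 4.93-fold lower (log2 -2.30, SE 0.27, adjusted p = 0.0418), each in 3 of 3 pairs. Rgs4 (-1.43, SE 0.15), Hs3st5 (-1.43, SE 0.18), Scg2 (-1.17, SE 0.12) and Wif1 (-1.04, SE 0.11) were lower, as was Scd1 (-1.46, SE 0.18), a fatty acid desaturase. Lgi2 (-1.21), Sv2c (-1.21), a synaptic vesicle protein, Kcnc2 (-1.06), a potassium channel of fast-firing neurons, and Hdac9 (-1.02), a histone deacetylase, completed the lowered genes, with adjusted p from 0.0411 to 0.0418. Higher with TTX were Gpnmb (0.98), a transmembrane glycoprotein, Lancl3 (0.81), Cryab (0.72), a small heat-shock protein, Jag1 (0.65), a Notch ligand, Prnp (0.56), the prion protein, and Kctd4 (0.52), with adjusted p from 0.0411 to 0.0462. Vgf was 3.77-fold lower in 3 of 3 pairs and did not pass (log2 -1.92, SE 0.30, adjusted p = 0.0548), though it did with culture as a random block (adjusted p = 0.0217). The paired limma fit called 62 genes, 9 higher and 53 lower. The fit of groups alone called 0, with 447 genes at an unadjusted p under 0.05 where chance gives 604, and 5 on the deposited scale. Leaving out any 1 knockdown pair also gave 0 in the paired fit.

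Cholesterol genes were again lower in 20 of 20 cases in knockdown (median -0.71), 9 called over all genes and 20 adjusted over the list alone. The adjusted p was 1.39e-21, and adjusted p = 0.26 with an estimated correlation. Potassium channels (22 of 24 lower, median -0.46, 1 called over all genes and 13 adjusted over the list alone) and presynaptic genes (25 of 26, median -0.33, 1 and 14) had adjusted p of 1.08e-09 and 1.13e-09. Late activity effectors (23 of 29, median -0.35, 3 and 7), postsynaptic scaffolds (21 of 23, -0.18, 0 and 0) and GABA receptors (15 of 17, -0.25, 1 and 7) had adjusted p of 6.84e-06, 0.000127 and 6.26e-05. GABAergic markers (13 of 17, -0.37, 1 and 8) and glutamatergic markers (11 of 14, -0.30, 0 and 7) had adjusted p of 0.000466 and 0.000268. Progenitor and cell-cycle genes were higher in 21 of 21 cases (median 0.39, 0 called over all genes and 14 adjusted over the list alone, adjusted p = 6.14e-11), for instance Prc1 (0.49, SE 0.07), a cytokinesis protein. With an estimated correlation these 9 lists had an adjusted p between 0.26 and 0.446.

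Further lists passed in knockdown at the preset correlation. Lower were NMDA and metabotropic receptors (median -0.33, adjusted p = 0.00177), AMPA receptors (-0.17, adjusted p = 0.0166) and calcium channels (-0.14, adjusted p = 0.0192). Sodium channels (-0.28, adjusted p = 0.0128), stress genes (-0.16, adjusted p = 0.0166) and protocadherins (-0.09, adjusted p = 0.00276) were lower as well. Astrocyte markers (0.16, adjusted p = 0.00418) and p53 targets (0.09, adjusted p = 0.0214) were higher. Over all genes 0 were called in each of these 8 lists. Adjusted over the list alone the counts were 7 for NMDA and metabotropic receptors, 1 for AMPA receptors, 4 for sodium channels (1 of them higher), 3 for stress genes, 15 for protocadherins and 3 for p53 targets, and 0 for the other two. All 8 lost the call, with an adjusted p between 0.26 and 0.655 with an estimated correlation. The protocadherin list repeats measurements within its Pcdha and Pcdhg clusters, so its count is not one of separate genes. Immediate early genes had a median of -0.03 while their test pointed up (adjusted p = 0.921), and the retinoic acid list had a median of -0.04 and a mean of 0.00 under a test pointing up (adjusted p = 0.856). Oligodendrocyte, ribosomal, oxidative phosphorylation, H3K9 methylation, interferon, microglia and vascular lists did not pass either (adjusted p from 0.111 to 0.993).

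The third comparison set the TTX response in knockdown against that in wild-type. Of the 282 genes that fell in wild-type 276 were also lower in knockdown, with medians of -0.69 and -0.53, and of the 102 that rose 97 were higher. The lowered calls shared 50 genes against 1.24 for independent calls, and the raised calls shared 7 against 0.076. The calls of both genotypes came from 1 fit that shares the spread of each gene, so they were not independent. Across all 12073 genes, which are not independent replicates, the changes had a Pearson r of 0.603 and a Spearman rho of 0.575. The interaction term called 0 genes in limma in either fit, with 53 genes at an unadjusted p under 0.05 with groups alone and 455 with the pairs, where chance gives 604. On the planned scale of the deposited values these fits called 7 and 6. The smallest p with groups alone belonged to genes that did not pass: Tbx4 (log2 1.59), Cntnap5a (0.80) and Trpm8 (1.15) on the positive side and LOC363337 (-2.63), Cpne9 (-1.34) and Lca5 (-0.67) on the negative, with adjusted p from 0.682 to 0.974 in the fit with pairs. Except for Lca5 (246) their means were low: 9.40 for Tbx4, 49.3 for Cntnap5a, 16.6 for Trpm8, 6.80 for LOC363337 and 17.0 for Cpne9. The list of immediate early genes had a positive interaction (18 of 24 positive, median 0.12, adjusted p = 0.0437), as did late effectors (21 of 29, 0.10, adjusted p = 0.00447) and ribosomal proteins (70 of 93, 0.11, adjusted p = 0.000871), and protocadherins a negative one (22 of 39 negative, -0.10, adjusted p = 0.00382). All 4 were lost, at adjusted p = 0.772 or 0.826 with an estimated correlation. The protocadherin count and its p at the preset correlation take repeated measurements within the Pcdha and Pcdhg clusters as separate genes. With the pairs these 4 lists had adjusted p of 0.0192, 0.00624, 4.89e-07 and 0.0166, and 5 more passed. Those were oligodendrocyte (13 of 14 negative, -0.33, adjusted p = 0.000429) and microglia markers (6 of 7 negative, -0.52, adjusted p = 0.0463), progenitor genes (18 of 21 positive, 0.10, adjusted p = 0.0104), p53 targets (12 of 15, 0.06, adjusted p = 0.0169) and oxidative phosphorylation (51 of 75, 0.06, adjusted p = 0.0192). All 9 were lost, at adjusted p from 0.292 to 0.73 with an estimated correlation, with 0 members called over all genes and 1, a ribosomal gene with the pairs, adjusted over the list alone. The microglia difference came mostly from wild-type pair 1. Relative to all libraries its list mean moved from -0.15 to 1.69 with TTX. Wild-type pairs 2 and 3 moved from -0.74 to -0.49 and from 2.17 to 2.23. The ribosomal list moved from 0.45 to 0.18, 0.145 to 0.155 and -0.07 to -0.13 in wild-type pairs 1, 2 and 3. In knockdown pairs it moved from -0.316 to -0.319, -0.25 to -0.18 and 0.18 to 0.15. Oxidative phosphorylation moved from 0.08 to -0.20, 0.03 to 0.07 and -0.08 to -0.17 in wild-type. Its knockdown pairs moved from 0.01 to -0.06, -0.200 to -0.197 and 0.41 to 0.31. In both lists wild-type pair 1 moved most and the genotypes overlapped.

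**Figure D3:**
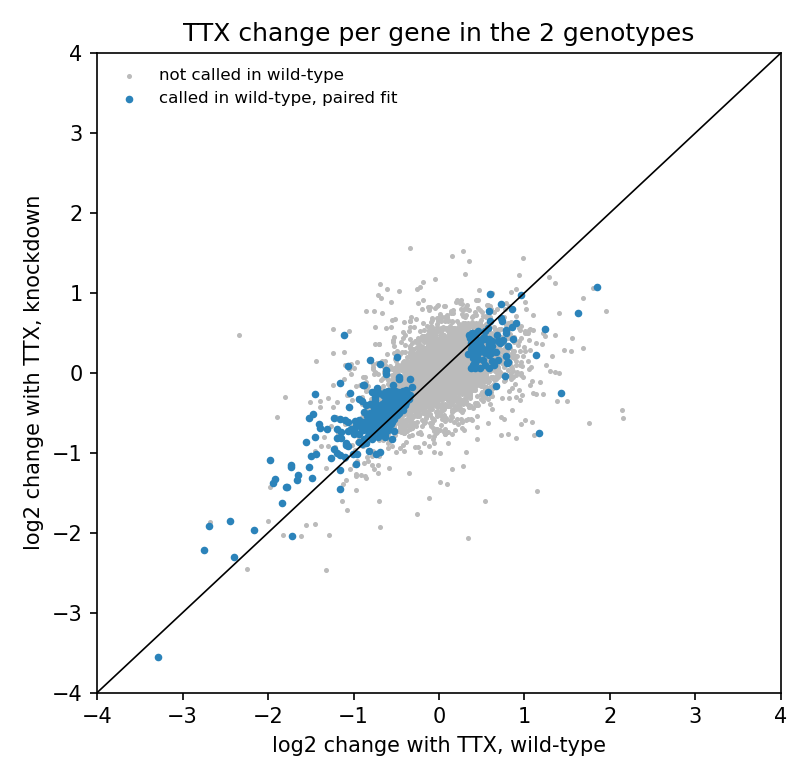
Log2 change with TTX in wild-type (x axis) against knockdown (y axis) for 12073 genes, with blue for the 384 called in wild-type pairs and a line of equality. Pearson r across genes was 0.603, and 71.7% of genes had the same sign.

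The fourth comparison asked how knockdown and wild-type differ before and after TTX. Over both treatments Mmp2 (NM_031054), a matrix metalloproteinase, was higher by 1.58 on the log2 scale (SE 0.19, adjusted p = 0.0449), at 778 to 1512 in 6 knockdown and 284 to 544 in 6 wild-type libraries. Nrsn2 (NM_001109561), encoding neurensin-2, a vesicle membrane protein of neurons, was higher by 0.94 (SE 0.12, adjusted p = 0.0449). Cntnap5a, a neurexin-related adhesion gene below the mean of 100 in the naming rule and named after its values were seen, was higher by 0.88 (SE 0.11, adjusted p = 0.0449). These 3 were the calls of limma with groups alone, which treats the TTX and untreated libraries of a culture as separate and had 2033 genes at an unadjusted p under 0.05. With culture as a random block all 3 were lost (adjusted p = 0.63 each), leaving 0 calls in limma and 854 genes at an unadjusted p under 0.05. Within untreated and within TTX libraries limma called 0 genes, with 736 and 986 at an unadjusted p under 0.05. On the deposited scale groups alone called 14 genes over both treatments, 9 in untreated and 9 in TTX libraries. In untreated and in TTX libraries, protocadherins (34 of 39, median 0.28, adjusted p = 9.89e-08; 33 of 39, 0.14, adjusted p = 0.00367) and cholesterol genes (19 of 20, 0.28, adjusted p = 4.3e-06; 19 of 20, 0.21, adjusted p = 0.00142) were higher. Ribosomal proteins were lower in both (71 of 93, -0.29, adjusted p = 1.8e-10; 63 of 93, -0.17, adjusted p = 0.000429). Late effectors did not pass in untreated libraries (median 0.19, adjusted p = 0.0836) and were higher with TTX (24 of 29, 0.35, adjusted p = 0.000685). Over all genes 0 members of these 4 lists were called, and adjusted over the list alone 1 late effector was, with TTX. With culture as a random block 0 late effectors were called that way, and 2 ribosomal genes were, lower in untreated libraries. All 7 calls were lost, at adjusted p = 0.772 or 0.825 with an estimated correlation. The protocadherin counts include repeated measurements within the Pcdha and Pcdhg clusters.

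The oligodendrocyte and microglia lists had the largest median differences between the genotypes. All 7 microglia markers were lower in knockdown (median -1.54, adjusted p = 0.000721), with 0 called over all genes and 3 adjusted over the list alone. Of 14 oligodendrocyte-lineage markers 12 were lower (median -1.82, adjusted p = 0.000899, 0 called over all genes and 6 adjusted over the list alone, 1 of them higher). Both had an adjusted p = 0.772 with an estimated correlation. With culture as a random block, adjustment over the list alone called 0 microglia markers. It called 5 oligodendrocyte markers lower and 1 higher. Myrf, the myelin gene regulator, was at 107 to 476 in knockdown and 495 to 1852 in wild-type (log2 -1.86, SE 0.43, adjusted p = 0.127). Per culture the oligodendrocyte list lay at 1.35, 0.03 and 1.03 in wild-type and -2.33, -0.22 and 0.15 in knockdown. The microglia list lay at 0.77, -0.62 and 2.20 in wild-type and -0.74, -0.72 and -0.90 in knockdown. Its members averaged only 4.63 to 30.6 read equivalents, near the filter of 10, so the size of its difference is poorly determined. In knockdown libraries the mean log2 level of the list was 1.60 to 1.97. Members could pass the filter through wild-type libraries alone, which favours a lower value in knockdown.

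**Figure D4:**
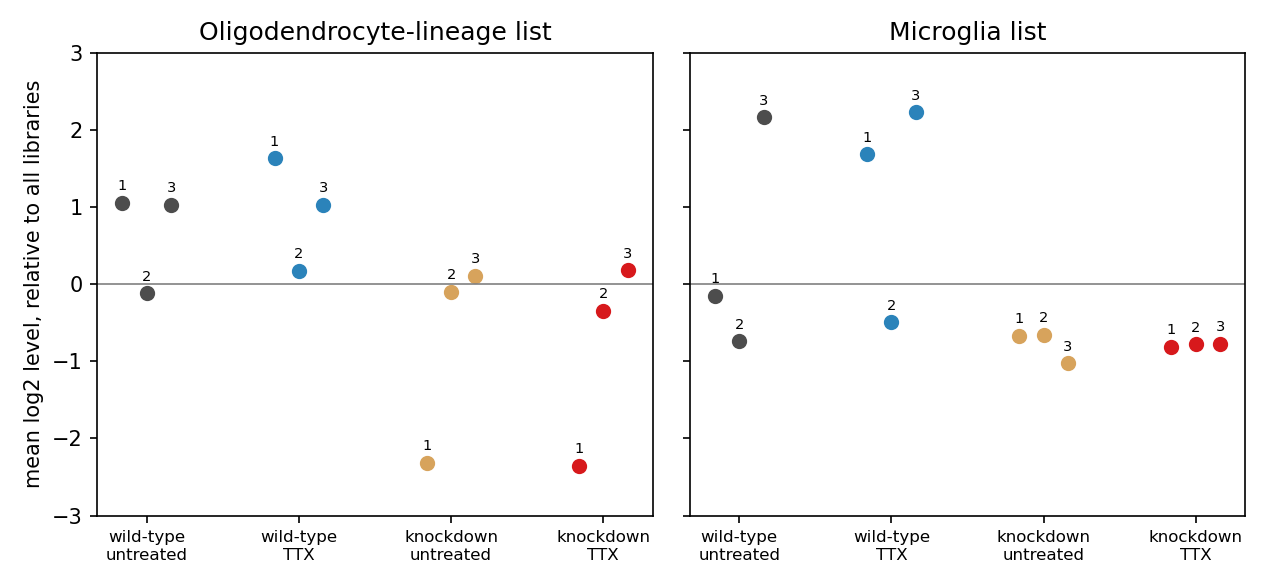
Mean log2 level of the oligodendrocyte-lineage (left) and microglia (right) lists in each library, relative to all libraries, numbered by replicate. Wild-type replicate 3 held the highest microglia values, with a culture mean of 2.20, and knockdown replicate 1 the lowest oligodendrocyte values, with a culture mean of -2.33.

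Presynaptic genes were higher in 23 of 26 cases (median 0.29, adjusted p = 0.000721), postsynaptic scaffolds in 20 of 23 (0.22, adjusted p = 0.00447) and glutamatergic markers in 12 of 14 (0.39, adjusted p = 0.00157; 0 called over all genes and 4 adjusted over the list alone). Cholesterol genes were higher in 19 of 20 cases (0.23, adjusted p = 3.8e-05), GABA receptors in 13 of 17 (0.18, adjusted p = 0.00908), sodium channels in 9 of 10 (0.23, adjusted p = 0.0437) and interferon genes in 18 of 20 (0.40, adjusted p = 0.0027). Immediate early genes (17 of 24, median 0.31, adjusted p = 0.0193) and late effectors (23 of 29, 0.30, adjusted p = 0.00447) were higher too. Protocadherins, cell-adhesion genes in 3 clusters, were higher in 33 of 39 cases (0.22, adjusted p = 1.15e-05). The 13 measured Pcdha and 13 Pcdhg transcripts of this list had median correlations of 0.999 across libraries within each cluster, so they are not separate measurements, and the 11 Pcdhb genes had a median of -0.10. The ribosomal list, which took in 10 other genes by name, was lower in 70 of 93 cases (-0.23, adjusted p = 2.08e-07), stress genes in 11 of 19 (-0.26, adjusted p = 0.0354) and H3K9 methylation genes, Ehmt1 among them, in 13 of 19 (-0.09, adjusted p = 0.0437). Over all genes 0 members of these 13 lists were called. Adjusted over the list alone the counts were 18 in the ribosomal list (1 of them higher), 5 for stress genes, 3 for cholesterol genes, 2 for GABA receptors, 2 for H3K9 methylation genes, 1 for each activity list and 0 for presynaptic, postsynaptic, sodium channel, interferon and protocadherin genes. With culture as a random block these counts were 3 for glutamatergic markers, 2 in the ribosomal list, 2 for stress genes and 0 for the other lists. With the libraries of each culture averaged all 13 passed at the preset correlation, with adjusted p from 5.34e-07 to 0.0476. All 13 of these calls were lost, at adjusted p = 0.772 with an estimated correlation. In each of the 13 the culture means of the genotypes overlapped. Knockdown culture 3 lay at -0.26 for presynaptic genes, -0.18 for postsynaptic scaffolds and 0.17 for ribosomal proteins, against 0.03, -0.03 and -0.10 in wild-type culture 3. Interferon genes lay at 0.89, -0.12 and -0.00435 in knockdown and 0.60 in wild-type culture 3, and stress genes at -0.42, -0.10 and -0.03 in knockdown and -0.16 in wild-type culture 3. Vascular and retinoic acid lists had medians of -0.08 and -0.01 but means of 0.19 and 0.24, under tests pointing up (adjusted p = 0.88 and 0.787). NMDA and metabotropic receptors and progenitor genes had medians of 0.12 and 0.02 but means of -0.03 and -0.005, also under tests pointing up (adjusted p = 0.962 and 0.502). AMPA receptor, GABAergic marker, calcium channel, potassium channel, astrocyte, p53 and oxidative phosphorylation lists did not pass either (adjusted p from 0.0527 to 0.385). With cultures averaged, GABAergic markers and potassium channels (camera adjusted p = 0.038 each) and oxidative phosphorylation (0.0476) did pass. With groups alone and an estimated correlation their adjusted p was 0.772, 0.852 and 0.897.

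The authors' deposited tables name genes by how TTX lowered them, chosen on these same libraries, so the counts that follow are not independent evidence. The gene lists there hold 74, 127 and 241 genes, of which only the 61, 99 and 196 named in the enriched terms are counted here. Of the 61 listed as blocked by the shRNA, 61 were lower with TTX in both genotypes, with medians of -0.60 in wild-type and -0.37 in knockdown. The paired fit called 35 of them in wild-type and 2 in knockdown, while the interaction term called 0 and was positive for all 61 (median 0.21). The listed genes included Kcnc4, a potassium channel. Of the 99 listed as lowered in both genotypes, the paired fit called 79 in wild-type and 33 in knockdown, cholesterol enzymes such as Lss and Cyp51 among them. Of the 196 listed as lowered in wild-type it called 138 in wild-type and 40 in knockdown. From the p of the authors' deposited table, 89 genes passed a Benjamini-Hochberg 0.05 for TTX in wild-type, 82 of them called in the paired fit, and 50 passed in knockdown, 25 of them called. For knockdown 633 passed over both treatments (295 higher, 338 lower), 48 with TTX and 5 in untreated libraries, where limma with groups alone called 3, 0 and 0 and with culture as a random block 0, 0 and 0. Over both treatments these fits had 2033 and 854 genes at an unadjusted p under 0.05. The authors' deposited table gave Ehmt1 a p of 5.78e-05 for 6 libraries against 6. Whether that test took account of the pairing by culture is not given in the sources used here.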

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

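The tests of an Ehmt1 order against Grk1, of glial markers, of flips within pairs and of whole cultures were chosen after the results were seen, and the other tests before.

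Genes lowered by TTX in wild-type responded less in knockdown, with medians of -0.69 and -0.53, while genes lowered in knockdown had medians of -0.79 in both genotypes. Picking the 200 most lowered genes on 2 wild-type pairs and measuring the held-out pair gave -0.66 in wild-type and -0.63 in knockdown. The mean difference over 3 hold-outs was -0.0353 (SD 0.0613), so a smaller response of this size may come from picking genes on the wild-type pairs. With genes picked on knockdown pairs the difference was 0.0140 (SD 0.132). A lower untreated level in knockdown was argued against, since the picked genes were higher there in all 3 hold-outs, by at least 0.205. A difference of single genes with knockdown remains open, as the interaction called 0 genes.

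Grk1, the rhodopsin kinase, was chosen after its values were seen: it lay at 70.2 to 1052 in knockdown and 1.34 to 36.2 in wild-type (log2 5.50, SE 0.90, adjusted p = 0.108). The highest change among the 4 nearest measured genes was 0.00312 on the log2 scale. Reading-in from a neighbour still cannot be told apart from a change of the gene. Gas6 averaged 4585 and Tfdp1, on the other side, 2452, both above the highest Grk1 level. Either could read in at an unchanged level of its own, and the strands of the neighbours were not checked. Tmem255b, which lies between Gas6 and Grk1, had a change of -1.04 (SE 0.62). How far reading-in would raise Tmem255b was not tested, and its value does not bear on Tfdp1. Sequence of the knockdown construct counted as Grk1 cannot be told apart either, without the construct's sequence. The order of Grk1 over the 3 knockdown cultures was not the reverse of that of Ehmt1, which the test scored 0. An effect of Ehmt1 on Grk1 stays open and untested.

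The oligodendrocyte list was lower in knockdown, with a median of -1.82. The 17 astrocyte members changed by -0.12 at the median (SD 0.23, from -0.45 to 0.25). The oligodendrocyte members (SD 1.27) lay at -1.70 relative to them, beyond the larger SD, which was the limit of the test. These SDs are over genes and not over cultures, so the test cannot exclude a lower share of every non-neuronal cell type. Tests of the signs of list medians and of the gap between both lists per culture were replaced after their results were seen. That gap differed by -1.52 between genotypes, short of 2 pooled SD of 0.926 between cultures. The culture means of the oligodendrocyte list overlapped between genotypes, so differences between cultures in this lineage stay open, as does an untested effect of the knockdown on it.

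The TTX response of 4 lists with groups alone, and of 9 with the pairs, differed between genotypes by the interaction test with a preset correlation. The adjusted p was 0.0437 for immediate early genes, 0.00447 for late effectors, 0.00382 for protocadherins and 0.000871 for ribosomal proteins, and each was lost at adjusted p = 0.772 or 0.826 with an estimated correlation. With the pairs these 4 had an adjusted p of 0.0192, 0.00624, 0.0166 and 4.89e-07. The other 5 were oligodendrocyte (adjusted p = 0.000429), microglia (0.0463), progenitor (0.0104), p53 (0.0169) and oxidative phosphorylation lists (0.0192), and all 9 were lost at adjusted p from 0.292 to 0.73 with an estimated correlation. The microglia difference came mostly from 1 wild-type pair. In the ribosomal and oxidative phosphorylation lists the same pair moved most, and the pairs of the genotypes overlapped. The Pcdha and Pcdhg entries of the protocadherin list are not separate measurements. Tbx4, LOC363337 and Cpne9 moved one way in all 3 wild-type pairs and the other way in all 3 knockdown pairs, with interactions of 1.59, -2.63 and -1.34 that did not pass. Their means of 9.40, 6.80 and 17.0 read equivalents lie near the filter of 10, so these folds are poorly determined. Over all genes 185 had such opposite pairs, where signs at random give 377. A TTX response shared by the genotypes lowers that count, and 2839 genes had all 6 pairs moving one way. The count therefore cannot decide whether some genes respond in opposite ways.

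Other splits of the libraries tested the counts. For TTX in wild-type with groups alone, 2 of 10 splits gave as many as the 4 calls, and the highest other gave 196, a split that parted 1 pair. The remaining splits that parted 1 pair gave 0, and the cause of the 196 was not tested. The other 3 splits that part all 3 pairs gave 0. For TTX in knockdown, knockdown in untreated and knockdown in TTX the real count was 0, so 10 of 10 splits gave as many, the highest other being 0. These splits of 3 against 3 are too few for a share under 0.05. For knockdown over both treatments 3 of 100 splits gave as many as 3 calls (highest other 83), but with cultures kept whole 4 of 10 did (highest other 214), and 10 groupings are too few for a share under 0.05. The share of 3 in 100 excludes chance only if the libraries of a culture count as separate. For the interaction the real count was 0 and 100 of 100 splits gave as many (highest other 396). Flipping treatment within pairs gave 384 real calls in wild-type and 62 in knockdown, each the 1 of 4 flips to do so, with a highest other of 0, and 4 flips are too few for a share under 0.05. For the paired interaction 32 of 32 flips gave as many as 0 calls, and the highest other, 1570, was the flip that turns the interaction into the summed TTX effect.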

How the results depend on the processing

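Read equivalents were chosen after the form of the values was seen, and the deposited scale was the planned one. Alternatives chosen after the data were seen were all distinct entries, culture blocks, averaged cultures, the absence of wild-type culture 3 and each test on the pairs, and the others were planned. No called gene or list reversed. TTX in wild-type with groups alone called 4 genes. It gave 2 with quantile normalization, 2 with no filter, 0 with the 2 groups alone, 11 on the deposited scale and 2 with all distinct entries. It gave 384 with a block within genotype, 730 with culture as a random block, 2 with no wild-type culture 3 and 112 in that random block. TTX in knockdown called 0, then 3 with no filter, 5 on the deposited scale, 62 with a block within genotype and 349 with a random block. Knockdown in untreated called 0, then 1 with no filter and 9 on the deposited scale. Knockdown in TTX called 0, then 2 with no filter, 9 on the deposited scale, 2 with no wild-type culture 3 and 1 in that random block. Knockdown over both treatments called 3, then 6 with no filter, 1 with trend and robust, 15 with a block by number over both genotypes and 14 on the deposited scale. It called 0 with a random block, 5 with no wild-type culture 3, 0 in that random block and 0 with cultures averaged. The interaction called 0, then 7 on the deposited scale and 1 in the random block with no wild-type culture 3.

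With the pairs, TTX in wild-type called 384 genes, then 11 with no filter, 712 with a filter of 50, 1114 with trend and robust and 24 on the deposited scale. TTX in knockdown called 62, then 139 with a pseudocount of 5, 5 with no filter, 356 with a filter of 50, 648 with trend and robust and 11 on the deposited scale. The paired interaction called 0, then 6 on the deposited scale. Leaving out 1 library gave 0 to 3 calls for TTX in wild-type, 0 to 1 for knockdown in TTX and 0 to 2 for knockdown over both treatments. Leaving out 1 pair gave 31 to 58 in wild-type and 0 to 0 in knockdown. The cause was not tested in any of these cases, except that blocks remove the spread between cultures by construction and fewer libraries leave fewer degrees of freedom. The deposited scale makes values under 1 read count, by construction.

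Single genes with small changes that did not pass reversed, mostly when 1 library was left out. The ranges were -0.0118 to 0.30 for Ehmt1 with TTX in knockdown and -0.19 to 0.12 for its interaction. For Ehmt2 they were -0.12 to 0.0787 with TTX in wild-type (0.00579 with quantile normalization), -0.0255 to 0.18 with TTX in knockdown, -0.16 to 0.0626 for knockdown in TTX and -0.0217 to 0.21 for the interaction. Bdnf ranged from -0.55 to 0.28 for knockdown in untreated and -6.55e-05 to 0.41 over both treatments. Arc ranged from -0.58 to 0.27 with TTX in wild-type and -0.68 to 0.16 for the interaction.

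Of the single-gene values 1081 stayed on their side of the threshold, 22 reversed, 67 gained a call and 65 lost one. Of the list values 167 stayed and 81 lost the call, 73 of them with an estimated correlation. Another count tool was not run, since the values are covered bases and not reads. Small folds were often missed: in simulated data the paired fit recovered 32% of 1.5-fold changes.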

Other observations

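Nothing in this part was planned: each value was looked up after the data were seen.

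The transcript of LOC102723236, a 7SL RNA of the signal recognition particle, took 1.30% to 2.25% of the coverage in knockdown libraries and 3.00% to 6.43% in wild-type libraries. Cd24, a cell-surface glycoprotein of immature neurons, had a log2 difference of 1.25 between knockdown and wild-type (SE 0.34, adjusted p = 0.154). Nrgn, a calmodulin-binding protein of dendrites, differed by 1.08 (SE 0.20, adjusted p = 0.112) and Lpar1, a lysophosphatidic acid receptor, by -3.18 (SE 0.56, adjusted p = 0.112). The first principal component held 33.7% of the variance and set both libraries of wild-type culture 3 apart from the others. Between genotypes 1510 genes had culture means that did not overlap, where 10% of genes, 1207, do so by chance.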
